A study of Mus musculus with 2 samples.

How the data were processed

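Mouse heart muscle cells were profiled in 2 studies. Per the labels, in both, hearts were digested on a perfusion apparatus for 9 minutes at 1.5 mL per minute, cells were sorted into 96-well plates, and RNA was tagged with a 6-base cell barcode and a 10-base UMI and amplified for 17 PCR cycles. For the fixed cells, 800 µL of 100% ethanol was added to cells in 200 µL of buffer, per the labels' protocols. The multichamber animals were about 3 months old.

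The authors deposited counts: a table of UMI counts and a table of read counts per gene and cell barcode for each study, not normalized, with per-cell tables that add the chamber or fixation label, the library and totals. The deposited per-cell tables also give percent values, such as the percent of a cell's UMIs from ERCC spike-in RNA; these were not used for results. STAR 2.5.4b, featureCounts and the genome build GRCm38 are named in the submitters' processing notes, without their order. The annotation release, strand setting and UMI collapsing tool are not given in the sources used here. The tables held 24522 gene IDs in the multichamber and 22679 in the live and fixed study, of which 24489 and 22648 matched a gene symbol of GENCODE M21, which also gave coordinates. Overlapping and antisense genes cannot be told apart where strand was not used in counting. The 45 barcode columns without a cell label were left out of all comparisons.

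Groups came from the deposited chamber and fixation labels. Cells with at least 1000 gene UMIs and 500 genes (spike-ins excluded) were kept and their UMIs were summed per group. Levels are CPM of nuclear-encoded UMIs, with mitochondrially encoded genes outside the total, and log2 ratios used a pseudocount of 5 CPM, which understates ratios of low genes. Cells are not replicates and no animal is named, so no test was run. Ratios carry exact 95% Clopper-Pearson intervals of the share of the summed counts, list medians carry intervals from Poisson redraws of the counts, and per-cell medians carry order-statistic intervals; all cover counting error only. With no UMI on 1 side, a floor of 3 counts over the pool was used. No doublet caller was run; cells rich in other cells' RNA were left out in alternatives. Levels between the studies were compared only to find loci that differ with the study, and no biology is read from them: unprocessed pseudogenes took 25.8% of nuclear-encoded UMIs in live and 21.8% in fixed cells, against 0.344 to 0.549% in the 4 chambers, and mt-Atp6 stood at 17.6 CPM in ventricle-labelled cells and 4684 CPM in the other study. The cause of these differences was not tested.

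For 32 gene lists of cell types, contractile, metabolic and stress genes, the median log2 ratio of members with at least 30 UMIs was set against 10000 random lists matched on mean expression in 20 bins (seed 1), as a description of these pools. Members at least 1.5-fold apart were counted. Genes were named by a fixed rule: the 10 highest and 10 lowest log2 ratios among genes with at least 30 UMIs and 50 CPM on the higher side (between atria and ventricles, only where both atrial pools lay on the same side of both ventricular pools, ranked by the nearest pools), all members of 4 lists (atrial, ventricular, left and right patterning, sex), and of each other list the 4 most abundant and the 2 with the largest ratio. Predicted genes were counted but not named, and 1 result under this rule is not reported here. The groups, the filter, the lists, this rule and the first set of alternatives below were fixed before the data were examined. Which lists the text leads with was decided afterwards.

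Alternatives were other totals (all UMIs, edgeR TMM, median-of-ratios), equal weight per cell, read counts, other pseudocounts, cell filters and gene minimums, each library left out in turn, and cells over 2% non-myocyte RNA left out. Added after the data were seen were cells with at least 20000 UMIs only and cells over 0.5% mesothelial RNA left out. Also added then was leaving out the top cell of each gene. A further added setting left study-dependent loci out of the total. These were genes over 8-fold apart between ventricle-labelled cells and the pooled live and fixed cells, or of pseudogene or ribosomal RNA type. Members of the gene lists and mitochondrially encoded genes were exempt, among them haemoglobin genes over 8-fold apart. For a list, this setting therefore changed only the total. The procedure was tested on simulated counts, drawn per gene and pool from Poisson distributions with the real means and depths. Intervals covered the true ratio for 96.0% of 11715 genes in the atrial to ventricular comparison. Of genes raised 2-fold, 98.0% had the right direction. The simulation held no variation between cells or libraries, so it checked the computation and counting error, not coverage under such variation. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.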

Results

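Single heart muscle cells of adult C57BL/6 wild-type mice were isolated by enzymatic digestion of the perfused heart, sorted on a cytometer built for large particles, and profiled by SCRB-seq, a plate-based method that counts the 3' ends of polyadenylated RNA with unique molecular identifiers (UMIs). The first study, called multichamber here, held 332 labelled cells in 4 libraries (A to D): 71 cells labelled left atrium (LA), 69 right atrium (RA), 96 left ventricle (LV) and 96 right ventricle (RV). The second study held 72 ventricular cells, 36 sorted live and 36 sorted after ethanol fixation. Cells with at least 1000 gene UMIs and 500 detected genes were kept. This left 56 LA, 44 RA, 91 LV and 90 RV cells, and 31 live and 35 fixed cells. The kept cells summed to 1446262 gene UMIs in LA, 733462 in RA, 4350660 in LV, 5259330 in RV, 2069946 in live and 2848772 in fixed cells. No animal is named for any cell, so each group is 1 pool without biological replicates. No difference was tested, and every interval given is a 95% interval that covers counting error only.

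Cells labelled atrial were recovered less often and held less RNA than cells labelled ventricular. The filter kept 78.9% of LA cells (exact binomial interval 67.6 to 87.7%) and 63.8% of RA cells (51.3 to 75.01%), against 94.8% of LV cells (88.3 to 98.3%) and 93.8% of RV cells (86.9 to 97.7%). Median gene UMIs per kept cell were 16146 in LA (interquartile range 3663 to 36249), 4436.5 in RA (2553 to 14585), 40953 in LV (24694.5 to 63571) and 50503 in RV (35179 to 77789). Median detected genes were 2354 in LA, 1009.5 in RA, 3719 in LV and 4177 in RV. Thinned to 5000 UMIs, the medians were 1322 genes in 36 LA cells, 1351 in 18 RA cells, 1257 in 89 LV cells and 1246 in 87 RV cells, so the order of the unthinned medians was not kept at equal depth. Gene UMIs per UMI of the ERCC spike-in RNA had medians of 23.0 in LA, 10.6 in RA, 107 in LV and 113 in RV. Mitochondrially encoded RNA took a median of 35.3% of gene UMIs in LA, 33.1% in RA, 39.6% in LV and 42.9% in RV.

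**Figure D1:**
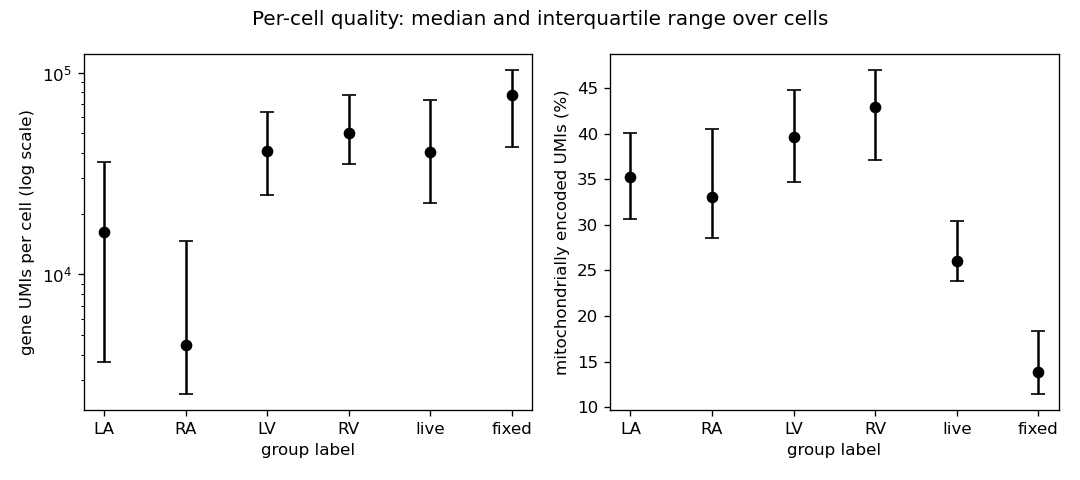
Gene UMIs per cell (left, log axis) and percent of gene UMIs from mitochondrially encoded genes (right) by group label; points are medians over cells past the filter and bars are interquartile ranges. RA has the lowest median UMI count of the chamber labels (4436.5), and fixed cells have a lower median mitochondrial share (13.8%) than live cells. The mitochondrial shares are not to be compared between the studies, whose counts on pseudogenes differ.

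Cells labelled atrial carried the ventricular myosin light chains at ventricular levels and almost no Nppa, Sln or Myl4 RNA. Myl2, the regulatory myosin light chain of ventricular muscle (chromosome 5, 122100951 to 122113472, plus strand, GRCm38), stood at 9321.6 UMIs per 1000000 nuclear-encoded UMIs (CPM) in LA, 11721 in RA, 10497 in LV and 10335 in RV. In summed pools the atrial to ventricular ratio of Myl2 was 0.973 (0.955 to 0.991), and that of Myl3, the ventricular essential light chain, was 0.982 (0.963 to 1.00). Nppa, which encodes atrial natriuretic peptide, gave no UMI in LA or RA cells, where the floor of 3 counts is 3.21 CPM in LA and 6.38 CPM in RA, and 1 UMI each in LV and RV. Myl7, the atrial regulatory light chain (chromosome 11, 5896637 to 5898782, minus strand), gave 81 UMIs in LA cells, of which 1 cell, rich in mesothelial RNA and low in Myl2 (679.6 CPM), held 63, none in RA, 3 in LV and none in RV. Sln, the atrial calcium pump regulator sarcolipin, gave 7 UMIs in LA, none in RA, 1 in LV and 3 in RV.

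Of the 11 measured genes of the ventricular myocyte list, none was at least 1.5-fold higher and 1, Irx3, was lower in the atrial pool (1.95-fold, 1.23 to 3.24). The list median log2 ratio was -0.040 (-0.13 to -0.021; percentile 63.4 among matched random lists), and it lay above 0 with all UMIs as the total (0.12), without library B (0.024) and without library D (0.0074). The median of all 11682 genes was -0.063, and 0.058 with all UMIs as the total, so list medians relative to all genes were 0.023 for the ventricular and -0.35 for the atrial myocyte list. The atrial list had a median of -0.41 (-0.57 to -0.19) over 10 measured genes, with Myl7 and Stard10 (1.70-fold, 1.28 to 2.24) at least 1.5-fold higher and Tbx5 and Myl4 at least 1.5-fold lower. None of 21 sarcomere genes reached 1.5-fold. Their median was -0.076 (-0.096 to -0.042), but 0.079 with all UMIs as the total, 0.089 without 3 mesothelial-rich cells, -0.19 without library C and -0.0048 without library B. None of 15 calcium-handling genes, 20 fatty acid oxidation genes or 26 nuclear-encoded oxidative phosphorylation genes reached it either, with medians of -0.053, -0.087 and 0.036; with all UMIs as the total these were 0.099, 0.064 and 0.19, and the last was -0.061 without library A. In all, 24 of 30 measured lists had medians within 1.5-fold.

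**Figure D2:**
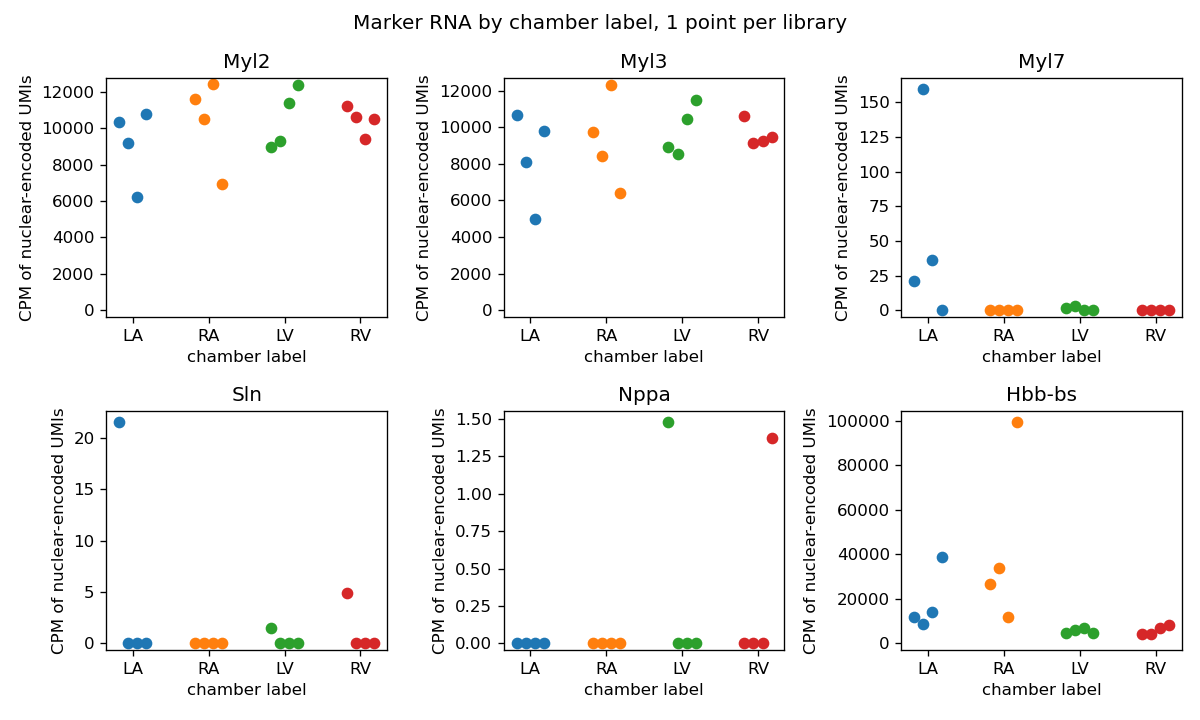
CPM of nuclear-encoded UMIs of 6 marker genes by chamber label, 1 point per library (A to D). Myl2 spans 6230.6 to 12422 CPM over the atrium-labelled and 8961 to 12367 CPM over the ventricle-labelled points, Myl7 shows only in LA apart from 3 UMIs in LV, and every atrium-labelled Hbb-bs point lies above every ventricle-labelled one.

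Erythroid, mesothelial, endothelial and mural genes differed between the labels. The fibroblast, macrophage and endocardial lists, with medians of -0.15, -0.097 and 0.16, gave no steady value: fibroblast -1.29 without the mesothelial-rich cells, macrophage -1.05 without library A and -0.89 without library B, and endocardial 0.65 without library C, -0.48 without library D and 1.58 with each cell weighted equally. All 5 measured erythroid genes were at least 1.5-fold higher in the atrial pool, with a median log2 ratio of 1.44 (1.43 to 1.51); Hbb-bs, a beta-globin gene (chromosome 7, 103826534 to 103828096, minus strand), was 2.71-fold higher (2.67 to 2.76). Haemoglobin genes are near-identical copies whose reads the counting could split, so single values are uncertain. Together the list took 3.45% of nuclear-encoded UMIs in the atrial and 1.26% in the ventricular pool. All 5 mesothelial genes were higher, with a median of 3.20 (2.86 to 3.57), or 2.57 without library B: Msln, mesothelin, by 17.1-fold (14.1 to 20.9) and Upk3b by 18.8-fold (15.3 to 23.1). Of 11 endothelial genes 8 were lower, with a median of -1.24 (-1.53 to -0.95, percentile 0), among them Flt1, a receptor for vascular endothelial growth factor, by 4.49-fold (3.00 to 7.01), Fabp4 by 4.21-fold (3.15 to 5.76) and Pecam1 by 3.27-fold (2.36 to 4.66). Another 2 of the 11 were at least 1.5-fold higher, among them Kdr by 3.01-fold (2.44 to 3.71). The pericyte marker Rgs5 was lower by 4.50-fold (2.93 to 7.27) and the mural list had a median of -0.61 (-1.17 to -0.38), which was -1.35 without library A. The erythroid median was 0.12 without cells over 2% non-myocyte RNA, a share that includes haemoglobin, and 0.052 in cells with at least 20000 UMIs; the endothelial median was -0.58 with each cell weighted equally. Without the 3 atrial cells that held over 0.5% mesothelial RNA, the mesothelial median was 0.099 and 10 of 11 endothelial genes were lower.

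Among single genes for which both atrial pools lay on the same side of both ventricular pools, the 10 furthest on the higher side were Muc16, Arsb, Upk1b, Fbln1, Isg20, Igfbp6, Rarres2, Ube2l6, Slc26a3 and 1 predicted gene. Muc16, a membrane mucin of mesothelium, was 36.7-fold higher (26.5 to 51.9), and Isg20, an interferon-stimulated exonuclease, 4.03-fold (3.08 to 5.27). In 4 of these 10 genes a single cell gave over 50% of the UMIs, and 5 were higher in all 4 libraries. The 10 furthest on the lower side were Fli1, Flt1, Ptprb, Rgs5, Cped1, Gsn, Zeb2, Sparcl1, Slc22a15 and Lama2. Fli1, an endothelial and blood cell transcription factor, was lower by 4.77-fold (2.93 to 8.30) and Lama2, a laminin chain, by 2.51-fold (2.02 to 3.15), and 8 of the 10 were lower in all 4 libraries. Among factors of cardiac development, Tbx20 was lower by 1.76-fold (1.38 to 2.27), Tbx5 by 4.30-fold (2.12 to 10.2) and Hand2 had a ratio of 1.11 (0.687 to 1.72).

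The left and right atrial labels differed in haemoglobin and mesothelial RNA. The haemoglobin difference was spread over many cells, and the mesothelial RNA came mostly from 2 cells. All 5 measured mesothelial genes were at least 1.5-fold higher in LA (median log2 2.75, 2.24 to 3.46; 3.51 without library A and 3.72 without library C), led by Upk3b (12.6-fold, 8.13 to 20.5) and Msln (9.98-fold, 6.78 to 15.3). Of 4 measured fibroblast genes 3 were higher, such as Dcn, which encodes decorin (7.22-fold, 4.98 to 10.8), and of 5 endothelial genes 4 were higher, such as Kdr (15.8-fold, 6.63 to 49.4). Of the 1337 mesothelial UMIs in atrial cells, 1 LA cell of library B held 723 and 1 of library C held 506. Those cells had 102715 and 61197 gene UMIs, mitochondrial shares of 4.01% and 3.60%, and Myl2 at 679.6 and 1288 CPM. Without cells over 0.5% mesothelial RNA, chosen after the values were seen, the mesothelial value was -0.40 on the 1 gene left to measure and the fibroblast median 0.055. The endothelial median of 1.33 was 3.38 without library A, 0.80 without those cells and 4.63 without cells over 2% non-myocyte RNA. Within libraries A, B, C and D it was 0.22, 2.69, 0.38 and -2.82. No UMI minimum was applied inside a library, and the library D value rests on very few UMIs. In that order, the libraries held 23, 22, 6 and 5 kept LA cells and 11, 8, 17 and 8 kept RA cells. Label and library are therefore partly confounded in the summed LA and RA pools.

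Sarcomere and calcium-handling genes took a lower share in the summed LA pool, without a steady sign across libraries or settings. Of 21 sarcomere genes 6 were lower and none higher by 1.5-fold, with a median of -0.37 (-0.42 to -0.30); Ttn, the giant sarcomere spring protein, was lower by 1.66-fold (1.61 to 1.71) and Actn2 by 1.81-fold (1.66 to 1.98). Calcium-handling genes had a median of -0.42 (-0.48 to -0.25), with Trdn, triadin, lower by 2.17-fold (1.96 to 2.41). Within libraries A, B, C and D the sarcomere median was 0.031, -0.15, -1.28 and 0.47; it was 0.054 without library C, 0.11 with each cell weighted equally and -0.13 without the mesothelial-rich cells; the calcium-handling median was -0.24 without library C, -0.080 with each cell weighted equally, 0.12 without the top cell of each gene and 0.55 within library D. Of the 5 measured erythroid genes 4 were lower in LA, with a median of -0.89 (-0.92 to -0.85) that was -1.87 without library C and -0.51 without library B. The list took 2.68% of nuclear-encoded UMIs in LA and 4.98% in RA, with medians of 1.81% per LA cell and 11.3% per RA cell; 26 of 56 LA and 34 of 44 RA cells held over 2%. The median of all 5715 genes was 0.10, and 0.021 with TMM factors, so the sarcomere median relative to all genes was -0.47.

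In the 10 genes with the highest LA to RA ratios (Gpm6a, Tmsb10, Abi1, a, Myl7, C3, Ano1, Loxl1, Igfbp5 and Cldn15), a single cell gave between 52.2 and 77.8% of the UMIs of each gene. Against a floor of 3 counts over the RA pool, Tmsb10 was at least 19.0-fold higher (exact lower limit 15.2) and Myl7 at least 13.6-fold higher (exact lower limit 10.8), and 63 of the 81 Myl7 UMIs came from the mesothelial-rich cell of library B. Igfbp5, which encodes a binding protein of insulin-like growth factors (chromosome 1, 72857932 to 72874884, minus strand), was 18.2-fold higher (13.3 to 25.6), but had a log2 ratio of -0.080 without the mesothelial-rich cells. The genes with the lowest ratios included Pard6a, Rlf, Slc4a1, Asns, Chuk, Dnajc16, Cidea and 2 predicted genes. The named ones rested on 5 to 8 UMIs in LA, and Slc4a1, the red cell anion exchanger, was lower by 11.5-fold (4.41 to 38.1). Without library C, Pard6a and Rlf had log2 ratios of 0.31 and 0.24.

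The left and right ventricular labels were close in nearly every group of genes, and across 10812 genes Pearson's r of log2 CPM was 0.952, where genes are not independent replicates. Of 29 measured lists 27 had medians within 1.5-fold. No ventricular myocyte gene of 10, and no sarcomere gene of 21, reached 1.5-fold, with medians of 0.018 (-0.035 to 0.050) and -0.053 (-0.080 to -0.029). The ventricular median was -0.060 with TMM, -0.082 with median-of-ratios factors, -0.0066 without library C and -0.050 without library D. The sarcomere median was 0.00099 with all UMIs as the total, 0.036 without library A, 0.029 without library B and -0.13 without library C. Myl2 had a ratio of 1.02 (0.999 to 1.03), Myh6 was lower in LV by 1.09-fold (1.07 to 1.11) and Ttn by 1.12-fold (1.11 to 1.14). The median of all genes was 0.034, and -0.050 with median-of-ratios factors.

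Some immediate-early and mural genes were higher in the summed LV pool, unevenly across libraries. Of 18 immediate-early genes, which respond within minutes to stress and growth signals, 3 were at least 1.5-fold higher and none lower, with a median of 0.21 (0.16 to 0.31, percentile 100.0). Klf4 was 3.04-fold higher (2.43 to 3.82), Socs3 2.29-fold (1.65 to 3.21) and Egr1 1.39-fold (1.26 to 1.53). Of 5 mural genes 3 were higher, with a median of 1.27 (0.75 to 1.52), among them Myh11, the smooth muscle myosin, 7.77-fold (3.27 to 22.4). Without library A the immediate-early median was 0.082 and the mural median 0.40; without library B the immediate-early median was 0.39. Within library C the mural median was -0.81, and within library B the immediate-early median was -0.0066. Endothelial genes had a median of 0.24 (-0.027 to 0.44), which was -0.68 without library A, -0.20 without library B and 0.72 without library C. Of 4 inflammation genes, Nfkbia (1.56-fold, 1.20 to 2.02), Icam1 and Cxcl1 lay above a ratio of 1 and Sod2 below it (0.974, 0.909 to 1.04).

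The genes with the highest LV to RV ratios were Igf2, Eln, Jag1, Ptprj, Lmo2, Cytl1, Mgp, Klf4, Ldb2 and Cmip. In 7 of them 1 cell gave over 50% of the UMIs, and 4 still stood 1.5-fold higher without the top cell of each gene. Igf2 was 13.7-fold higher (7.78 to 26.3), with 78.9% of its UMIs in 1 cell. Eln, Cytl1 and Mgp had log2 ratios of -0.16, -1.003 and -0.79 without library A. The genes with the lowest ratios were spread over more cells: Nkiras2, P4ha1, Mief2, Cnot6l, Pdlim3, Aqp1, Vps35, Phka1, Angpt1 and Phf20. Nkiras2, a regulator of NF-kappaB signalling (chromosome 11, 100619244 to 100627607, plus strand), was lower in LV by 2.83-fold (2.08 to 3.91), and P4ha1, a collagen prolyl hydroxylase, by 2.23-fold (1.70 to 2.95). Of these 10 genes 7 were lower in all 4 libraries, and 8 remained at least 1.5-fold lower without the top cell of each gene.

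Fixed ventricular cells held lower shares of immediate-early, nuclear-retained and mitochondrially encoded RNA than live cells. Of 16 immediate-early genes 13 were at least 1.5-fold lower and none higher, with a median log2 ratio of -1.10 (-1.23 to -0.91, percentile 0); Fos was lower by 3.78-fold (3.24 to 4.40), Zfp36 by 3.03-fold (2.46 to 3.76), Btg2 by 2.68-fold (2.32 to 3.10) and Egr1 by 2.53-fold (2.14 to 2.98). Malat1, a long non-coding RNA kept in the nucleus (chromosome 19, 5795690 to 5802672, plus strand), stood at 1200.2 CPM in fixed and 5446.6 CPM in live cells, 4.54-fold lower (4.35 to 4.74). Kcnq1ot1 was lower by 5.53-fold (2.93 to 11.2) and Neat1 by 1.18-fold (1.07 to 1.30), where Neat1 turned above 0 on the log2 scale with all UMIs, TMM or median-of-ratios scaling. Mitochondrially encoded RNA took a median of 13.8% of gene UMIs per fixed cell (12.4 to 17.9) and 26.1% per live cell (24.4 to 29.0). Relative to nuclear-encoded UMIs, the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 were lower by 3.10-fold (3.08 to 3.12) and 3.25-fold (3.21 to 3.28). Of 13 mitochondrially encoded genes 7 were at least 1.5-fold lower, against 4 with TMM or median-of-ratios factors. The list median of -0.63 was -0.062 with the latter. The mitochondrial shares and ratios depend on where reads were counted. Unprocessed pseudogenes stand in the nuclear-encoded total and took 21.8% of it in fixed and 25.8% in live cells. Whether their UMIs came from mitochondrial RNA was not tested, and any that did are missing from the mitochondrial share.

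The scaling moved every gene in this comparison. The median log2 ratio of 7860 genes was -0.31 with the nuclear-encoded total, -0.10 with all UMIs, 0.094 with TMM and 0.15 with median-of-ratios factors, so changes are also given relative to all genes. On that scale the medians were -0.79 for immediate-early, -1.43 for nuclear-retained, -0.31 for mitochondrially encoded, -0.30 for fetal and stress, and -0.24 for cardiac transcription factor genes. The nuclear-retained list had 3 measured genes, and its median is the value of Kcnq1ot1, which had 13 UMIs in fixed and 44 in live cells. With the nuclear-encoded total, the fetal and stress median was -0.62, with 5 of 9 genes at least 1.5-fold lower. It was -0.022 with 1 such gene without the top cell of each gene. Relative to all genes, the medians were 0.60 for glycolysis, 0.49 for the tricarboxylic acid cycle and 0.39 for oxidative phosphorylation. Their percentiles among matched random lists were 99.8, 98.8 and 96.9. The sarcomere median was 0.24 and the fatty acid oxidation median 0.21 on that scale. Their percentiles of 55.3 and 64.9 were near the middle of lists of like abundance. Immediate-early genes at least 1.5-fold lower numbered 12 with all UMIs, 9 with TMM and 8 with median-of-ratios factors.

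Genes of energy metabolism stood above the median of all genes in fixed cells. Of 15 glycolysis genes 2 were at least 1.5-fold higher and 1, Hk2, lower, against 12 higher with TMM and 13 with median-of-ratios factors; Eno3, muscle enolase, was 1.57-fold higher (1.43 to 1.74) and Ldhb 1.35-fold (1.25 to 1.46). Of 26 oxidative phosphorylation genes 1 was higher and none lower, against 11 and 15 higher with the same factors. Of 21 sarcomere genes 2 were higher and 7 lower, against 5 and 2 with TMM and 8 and 1 with median-of-ratios factors, and their median of -0.070 (-0.16 to -0.023) was 0.18 with all UMIs, 0.42 with TMM and 0.49 with median-of-ratios factors. Ttn was lower by 1.66-fold (1.63 to 1.70) and Lmod2, leiomodin, by 2.87-fold (2.57 to 3.21), while Myh6 had a ratio of 0.992 (0.969 to 1.02). The calcium-handling median of -0.42 was 0.053 with TMM and 0.12 with median-of-ratios factors, and genes at least 1.5-fold lower numbered 5 of 15, then 3 and 1. Among them Ryr2, the calcium release channel, was lower by 1.97-fold (1.87 to 2.07) and Cacna1c by 2.33-fold (2.19 to 2.47). Of 82 ribosomal protein genes 23 were lower and 1 higher, against 3 and 12 with TMM and 2 and 15 with median-of-ratios factors, with a median of -0.26 that turned to 0.22 with TMM and 0.29 with median-of-ratios factors.

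Among the highest and lowest single genes between fixed and live cells, many were predicted genes or loci flagged as study-dependent. Of the 10 highest, 8 were loci whose level differed over 8-fold between the 2 studies or whose type was pseudogene or ribosomal RNA. Among them were Mir6240 (7.70-fold, 7.46 to 7.95) and Celsr1 (9.49-fold, 6.83 to 13.5), and 1 other gene was predicted. The flag pooled live and fixed cells, so a rise in fixed cells itself counts towards the 8-fold. Mir6240 stood at 2721 CPM in live and 20952 CPM in fixed cells, against 1667 CPM in ventricle-labelled multichamber cells. The flag therefore does not separate a difference between studies from one between fixed and live cells. Of the 10 lowest, 9 were predicted genes and the other was Hbb-bs, with 91.9% of its UMIs in 1 live cell. Without the cell over 2% non-myocyte RNA, the erythroid median of -3.65 over 4 genes became 0.25 on 1 gene. Nppa (chromosome 4, 148000722 to 148002079) gave 40 UMIs in fixed and 1 in live cells, a ratio of 24.5 (4.15 to 991), with 38 of the 40 in 1 cell. Ventricular markers mostly stayed nearer to 1. Myl2 was lower by 1.17-fold (1.14 to 1.20), but had log2 ratios of 0.023 with all UMIs, 0.27 with TMM and 0.34 with median-of-ratios factors. Myl3 was 1.09-fold higher (1.06 to 1.13). Of 9 measured genes of the ventricular list, Irx4 was at least 1.5-fold higher (17.3 CPM in fixed, 9.4 in live cells) and Fhl2 lower (585 and 926 CPM). With TMM or median-of-ratios factors 3 of the 9 were higher and 0 lower. Fixed cells held 326 gene UMIs per spike-in UMI (252 to 409) and live cells 555 (446 to 645), while median genes at 5000 UMIs were 1235 and 1233. Both states were in 1 library with separate cell barcodes, so barcode and fixation cannot be told apart.

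**Figure D3:**
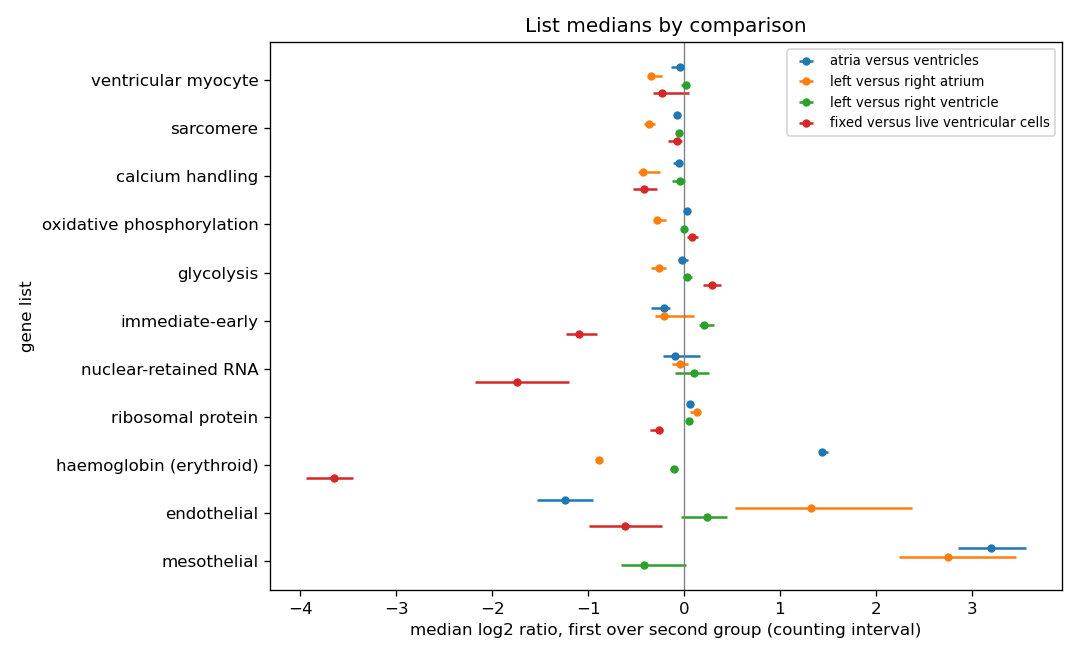
Median log2 ratio of 11 gene lists in the 4 comparisons, first group over second; points are medians over measured genes with the nuclear-encoded total, and bars are 95% counting intervals. Immediate-early and nuclear-retained RNA lie lowest among the lists of the fixed to live comparison apart from the haemoglobin list, whose value rests on 1 live cell. The fixed to live sarcomere, ribosomal, calcium-handling and ventricular myocyte medians change sign with the scaling. So do small medians of the chamber comparisons, such as sarcomere and ventricular ones.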

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

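All tests in this part were chosen after results were seen. Barcodes without a cell label, which no comparison uses, carried UMIs: 603 over 21 barcodes in the multichamber study, with at most 67 on 1 barcode, and 1269 over 24 barcodes in the live and fixed study, with at most 204. They were singled out because a signal stands in data outside the comparisons. The difference was not tested.

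Cells labelled atrial carried Myl2 at ventricular levels and almost no Nppa, Sln or Myl4. Free ventricular RNA in wells with little RNA of their own would leave deep cells with less Myl2. In cells with at least 20000 UMIs (33 atrial, 156 ventricular) the ratio was 1.01 (0.990 to 1.03). This argues against free RNA as the source in those deep cells, among them 9 RA cells. Shallower atrial-labelled cells, the larger part, were not tested, so free RNA stays open for them. In the deep cells Myl7 gave 74 atrial and 3 ventricular UMIs, 63 of the 74 from 1 cell. Sln gave 5 and 3, a ratio of 7.70 (1.50 to 49.6). A swap of atrial and ventricular labels within these plates would put atrial cells under ventricular labels, but 0 ventricle-labelled cells had Myl7, Myl4, Sln and Nppa together above 1000 CPM, against 2 LA and 0 RA cells. Carry-over of ventricular cells into the atrial samples may also give this pattern; it was not tested, and the labels' protocol names excision of the ventricle and no step for other chambers. No biological explanation was tested, and the chamber comparisons may not describe atrial muscle.

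Fixed cells held a lower share of immediate-early RNA than live cells. The study-dependent loci took 43.6% of nuclear-encoded UMIs in live and 46.0% in fixed cells. A change in the total moves all genes nearly alike, so it does not account for the list's place below other genes. Relative to all genes, the list median was -0.79 with these loci in the total and -0.7763 (-0.88 to -0.56) without them. That scale cancels the total, so leaving the loci out was no separate test. Only 1 of the 10 genes with the lowest fixed to live ratios was such a locus, so the others stayed in the total. An effect of the cell barcode set stays open. In the multichamber study the barcodes of the fixed set against those of the live set gave a mean list median of -0.2124 over 4 libraries. It was 0.071 and 0.47 in RV cells of libraries A and B, and -0.66 and -0.73 in LV cells of libraries C and D. The LV values have the sign of the fixed to live median of -1.10 and the RV values do not. The sign thus went with chamber and library, and the mean cannot decide. Live cells may keep making immediate-early RNA during handling, which these data hold no time course to test.

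Haemoglobin RNA took a larger share in cells labelled atrial. A like amount of free blood RNA in each well, diluted by less cell RNA, would give equal haemoglobin UMIs per spike-in UMI. Their median was 1.124 times as high in atrial as in ventricular cells of all libraries, but LA and RA lay on opposite sides of the ventricles. It was 0.3696 in LA and 0.9501 in RA cells, against 0.5526 in LV and 0.496 in RV cells, with overlapping interquartile ranges. In libraries A, B, C and D the atrial median was 1.69, 1.62, 0.817 and 4.12 times the ventricular one. The pooled ratio near 1 therefore does not show a like amount under each label. Dilution of free blood RNA may explain a part and cannot be told apart from red cell RNA that differs between samples. No biological explanation was tested.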

How the results depend on the processing

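Settings added after the data were seen were the 20000-UMI minimum, the mesothelial-rich cells, the study-dependent loci and the top cells. Of values on which the text leads, 149 stayed within their 95% counting interval, 96 moved outside it, in some cases across 0, and 1 reversed, meaning a sign change of a value at least 1.5-fold from a ratio of 1. Of the others 3557 stayed, 1199 moved and 15 reversed; counts and percentiles among these were held to limits of their own. Values in parentheses are log2 values with the settings of the report. Except where stated, the cause of each difference was not tested. No paired analysis was possible because no animal is named, so cells of different groups cannot be matched by animal. Labels can be compared inside libraries. Libraries A to D each hold all 4 chamber labels, but in uneven numbers. In that order they gave 23, 22, 6 and 5 kept LA cells and 11, 8, 17 and 8 kept RA cells. The summed LA and RA pools thus weight the libraries differently, and their ratios partly mix label with library. Medians within libraries, in the same order, were as follows. Between atrial and ventricular labels they were 0.076, -0.13, 0.094 and -0.28 for the ventricular myocyte, 1.72, 1.14, 0.86 and 3.26 for the erythroid, -0.067, -0.22, 0.083 and -0.26 for the sarcomere and -1.48, -1.35, -1.95 and -0.13 for the endothelial list. Between LA and RA they were -1.38, -1.99, 0.37 and -1.36 for the erythroid list. For the mesothelial list they were 0, 3.91, 4.34 and 0, where each 0 is a median gene without UMIs on either side. Between LV and RV they were -0.20, -0.24, 0.16 and 0.10 for the sarcomere, 1.82, 0.48, -2.20 and -0.35 for the endothelial and 0.73, -0.0066, 0.13 and 0.13 for the immediate-early list. Tests on animals were not run for the same reason, and leaving out a library was not run for live and fixed cells, which come from 1 library. Genes or lists without enough UMIs under a setting have no value there, except that medians within libraries had no UMI minimum.

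Between atrial and ventricular labels, the ventricular myocyte median (-0.040) was 0.12 with all UMIs, -0.30 at equal cell weight, -0.24 in reads, -0.012 at 5000 UMIs or more, 0.048 without mesothelial-rich cells, -0.20 without top cells and -0.094 to 0.024 over left-out libraries. The sarcomere median (-0.076) was 0.079 with all UMIs, -0.27 at equal cell weight, -0.032 at 20000 UMIs or more, 0.089 without mesothelial-rich cells, -0.098 without study-dependent loci, -0.25 without top cells and -0.19 to -0.0048 over left-out libraries. The erythroid median (1.44) was 1.59 with all UMIs, 2.96 at equal cell weight, 1.52 in reads, 1.66 without a cell filter, 0.76 at 5000 UMIs or more, 0.12 without cells over 2% non-myocyte RNA, 0.052 at 20000 UMIs or more, 1.60 without mesothelial-rich cells, 1.42 without study-dependent loci, 1.53 without top cells and 1.18 to 1.72 over left-out libraries. The endothelial median (-1.24) was -0.58 at equal cell weight, -1.83 in reads, -1.56 without cells over 2% non-myocyte RNA, -0.76 without top cells and -1.53 to -0.95 over left-out libraries.

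Between LA and RA, the sarcomere median (-0.37) was -0.45 with TMM, -0.43 with median-of-ratios factors, 0.11 at equal cell weight, -0.57 in reads, -0.43 at 5000 UMIs or more, -0.58 without cells over 2% non-myocyte RNA, -0.47 at 20000 UMIs or more, -0.13 without mesothelial-rich cells, 0.16 without top cells and -0.50 to 0.054 over left-out libraries. The glia median (1.90) was -0.39 at equal cell weight. The mesothelial median (2.75) was 0.31 at equal cell weight, 3.86 in reads, 4.50 without cells over 2% non-myocyte RNA, 3.61 at 20000 UMIs or more, -0.40 without mesothelial-rich cells, 1.72 without top cells and 2.53 to 3.72 over left-out libraries. Igfbp5 (4.11) was -0.080 without mesothelial-rich cells. Pard6a (-3.02) was 0.29 at equal cell weight and -3.06 to 0.31 over left-out libraries. Rlf (-2.86) was -3.28 to 0.24 over left-out libraries. Slc4a1 (-2.69) was 0.99 at 20000 UMIs or more. Mylk3 (-0.63) was 0.098 without top cells. Xist (-0.63) was -1.95 to 1.15 over left-out libraries.

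Between LV and RV, the sarcomere median (-0.053) was 0.00099 with all UMIs, -0.13 with TMM, -0.15 with median-of-ratios factors, -0.0060 at equal cell weight, -0.092 without cells over 2% non-myocyte RNA and -0.13 to 0.036 over left-out libraries. The endothelial median (0.24) was -0.16 in reads, -0.24 without top cells and -0.68 to 0.72 over left-out libraries. The inflammation median (0.73) was -0.066 with members of 1 UMI or more. Eln (2.72) was -0.16 to 3.29 over left-out libraries. Cytl1 (2.20) was -1.003 to 2.59 over left-out libraries. Mgp (2.12) was -0.21 without top cells and -0.79 to 3.04 over left-out libraries. Gja5 (2.07) was -0.048 to 2.47 over left-out libraries.

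Between fixed and live cells, the sarcomere median (-0.070) was 0.18 with all UMIs, 0.42 with TMM, 0.49 with median-of-ratios factors, 0.24 in reads, -0.0077 without study-dependent loci and -0.19 without top cells. The oxidative phosphorylation median (0.082) was 0.33 with all UMIs, 0.57 with TMM, 0.64 with median-of-ratios factors, -0.019 at equal cell weight and 0.36 in reads. The glycolysis median (0.29) was 0.53 with all UMIs, 0.78 with TMM, 0.85 with median-of-ratios factors, 0.13 at equal cell weight, 0.69 in reads and 0.39 at 20000 UMIs or more. The immediate-early median (-1.10) was -0.85 with all UMIs, -0.66 with TMM, -0.60 with median-of-ratios factors, -0.90 at equal cell weight and -0.78 without top cells. The nuclear-retained median (-1.74) was -2.18 with pseudocount 1 and -1.12 with members of 1 UMI or more. The erythroid median (-3.65) was 0.25 without cells over 2% non-myocyte RNA.

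The median of gene UMIs per cell was 34586.5 in LA cells and 19706.5 in RA cells at 5000 UMIs or more, and 2163.0 in RA without a cell filter, by construction of the filter. Leaving out cells over 2% non-myocyte RNA takes away haemoglobin-rich cells by construction, since that share includes haemoglobin. Where only 1 gene was measured (the glia list between LA and RA, the mesothelial list between LA and RA without mesothelial-rich cells, and the erythroid list between fixed and live cells without cells over 2% non-myocyte RNA), the value rests on that gene. RA has the fewest UMIs, so low ratios there rest on few counts.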

Other observations

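The tests of Xist and Y-linked RNA in this part were chosen after results were seen. Among 189 multichamber cells with at least 20000 UMIs, 25 held UMIs of Xist only, 35 of Y-linked genes only, 92 of both and 37 of neither; 78.6 with both would be found if the 2 were independent. In the live and fixed study 57 such cells gave 11, 14, 19 and 13, with 17.4 if independent. The strand setting of the counting is not given in the sources used here.

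Nppa in fixed cells came almost wholly from 1 cell, which held 92.7% of the UMIs of fixed and live cells. Across genes, Pearson's r of log2 CPM between pools was 0.800 for LA and RA (5715 genes), 0.863 for LA and LV (9435) and 0.888 for RA and RV (8816). It was 0.866 for LA and RV (9533), 0.878 for RA and LV (8646) and 0.877 for fixed and live cells (7860). Genes are not independent replicates. The gene sets and pool depths differ between pairs, so these values do not rank how alike the labels are.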
